A study of Homo sapiens with 12 samples.

How the data were processed

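Gene expression was measured in 12 samples of U937, an established human line with features of monocytes, on 1-colour oligonucleotide microarrays with 1 array per sample. Per the labels' protocols, the cells were kept for 24 h in supernatant of CCRF, a T cell line, which either held the extracellular vesicles (EVs) that line sheds or had been depleted of them, and TNF was added at 10 ng/ml or left out. The labels gave 4 groups of 3 replicates, called control (EV-depleted supernatant), EV, TNF and EV+TNF here. They do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Total RNA was amplified and labelled with the dye Cy3, per the labels' protocols.

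Per the file headers, the slides were read with Agilent Feature Extraction 11.0.1.1 and its protocol for 1-colour expression arrays, on a whole human genome design annotated on hg19. The deposited intensity values used were the processed signal, which that software had corrected for background and for trends across the slide, and the median brightness of each spot and of its local background. The deposited table of the whole series held log2 values, and their scale and centring were found by comparison with the arrays. Each of its columns followed the log2 processed signal minus that array's 75th percentile and minus the probe's median over the control arrays, with a Pearson r of at least 0.999 over 19085 matched probes of 19104, so that its direction was the same as here. Its column medians were 0, 0 and 0 for control, -0.006, -0.008 and 0.026 for EV, -0.01, 0.05 and -0.009 for TNF, and -0.028, -0.028 and 0.018 for EV+TNF. How the submitters tested these values is not given in the sources used here.

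Each array held 45015 spots, of which 1639 were controls and were left out. Spots marked as outliers by the software were left out unless all spots of the probe were so marked, and saturated spots were kept. Spots of the same probe were averaged on the log2 scale, which concerned 264 probes with 10 spots each. The value of each of the 41000 probes was the log2 processed signal minus the array's 75th percentile of it. A probe was kept where it was well above background on every array of at least 1 group, which 27535 probes were. Probes were named through RefSeq accessions, which 28321 probes carried, using a list of gene symbols of assembly GRCh38.p14. That list was used for names alone, and no coordinates are given because the builds differ. The accession matched a gene for 27294 probes of 18232 genes, and 13706 probes had no gene. The brightest kept probe stood for its gene, which left 13238 genes, and 4913 of these had several kept probes. Values outside reach were treated as bounds. Where a gene was not well above background on any array of a group, its difference is given as "at least" a fold, from the mean of the brighter group over that of the dim group with each dim value raised to the lowest signal well above background on its array.

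Differences between groups were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table (version 1.17.8) for reading. All 12 arrays entered a single linear model with a mean per group, which left 8 residual degrees of freedom and 2.51 prior ones. The 6 comparisons were EV, TNF and EV+TNF against control, EV+TNF against TNF, EV+TNF against EV, and the interaction of EV and TNF. The main effects of EV and of TNF, each averaged over both levels of the other treatment, were tested as well. P-values were adjusted by the method of Benjamini and Hochberg over the genes of each comparison, and a gene with an adjusted p under 0.05 is referred to as called. Errors are standard errors (SE) of the model for log2 fold changes and standard deviations (SD) for group means. Depth here lies in the signal over background and the number of arrays, and 3 arrays per group limit the precision. Data simulated over 13238 genes had the spread of these arrays but, unlike them, independent noise per gene, so real recovery may differ. The model recovered 61% to 70% of 2-fold and 89% to 95% of 4-fold changes in the 5 comparisons of single groups. It recovered 48% and 84% for the interaction, 81% and 98% for the EV and 85% and 97% for the TNF main effect.

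A set of 27 gene lists, which included markers of T cells and of other blood cells, was tested with camera of limma. It compares a list with all other genes, here with a preset correlation of 0.01 between genes and adjustment over all 216 tests. The same tests were run with a correlation estimated from the data. No list was chosen on these samples.

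The groups, the comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule each comparison of single groups named the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the groups, leaving out clone-like names. With fewer than 5 such genes, the 5 genes with the smallest unadjusted p were given as values. Up to 4 members of each list with the smallest adjusted p, and 10 known TNF response genes, could be named too. The main effects followed the same rule, with the arrays separate within each level of the other treatment and with the same sign, and this extension was chosen after the values were seen.

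The alternatives were quantile normalization, scaling on the median, normexp background correction (offset 50), the deposited table, no filter or a filter on all arrays, the mean of the probes of a gene, a floor on low values, the slide as a fixed or as a random block, the replicate number as a block, eBayes with a trend and robust spread, array weights, a change of at least 2-fold, the arrays of just the 2 groups, and each array left out in turn. The mean signal planned for normexp is not in the files used here, so the median signal took its place. On 3 arrays a few spots with a very high local background set the normexp correction of the whole array. After this was seen, local background over 2 times the array's median was set to that median, and the uncorrected version was kept beside it. Scaling on 6 of 10 spike-in probes and both treatments of 4 arrays that stood apart (as a block, or left out) were also added after the data were seen, as were the groups of histone and metallothionein genes. The criterion for RNA of T cells was changed after its value was seen. The array weights stopped before convergence.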

Results

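The study asked how EVs of a T cell line and the cytokine TNF act, alone and together, on U937 cells. Expression of 13238 genes was compared between control, EV, TNF and EV+TNF cells after 24 h, with 3 arrays in each of the 4 groups. The 75th percentile of the signal ran from 594 to 980 over the 12 arrays, and from 65.8% to 70.9% of the probes were well above background. Replicate arrays correlated with a Pearson r of 0.982 to 0.997 across genes, which are not independent replicates. The middle of the genes had residual SDs between 0.14 and 0.33 on the log2 scale.

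The arrays lay on 4 slides of 3 arrays. Slide 1 held control replicate 2, EV replicate 1 and EV+TNF replicate 3. Slide 2 held EV replicate 2, EV+TNF replicate 1 and TNF replicate 1, slide 3 held control replicate 3, EV replicate 3 and TNF replicate 2, and slide 4 held control replicate 1, EV+TNF replicate 2 and TNF replicate 3. A single array of each group stood apart from its replicates: control 2, EV 3, TNF 2 and EV+TNF 3 scored 32.1 to 35.8 on the first principal component of the residuals, which held 63.8% of the residual variance, and the other 8 arrays scored -24.3 to -11. These 4 arrays had 65.8% to 67.5% of their probes well above background, and the other 8 had 68.3% to 70.9%. The spike-in signal over the 75th percentile averaged 0.18 ± 0.055 (log2, SD, n = 3) in control, -0.23 ± 0.098 in EV, 0.27 ± 0.20 in TNF and 0.43 ± 0.31 in EV+TNF. Scaling on the spike-ins instead of the 75th percentile therefore moved the median of all genes. Against control it became 0.40 in EV, -0.089 in TNF and -0.28 in EV+TNF. It was -0.18 in EV+TNF against TNF, -0.67 in EV+TNF against EV and -0.59 in the interaction. The main effects had 0.11 for EV and -0.39 for TNF. All changes below are relative to the 75th percentile of each array. Within slide 1 for EV against control and EV+TNF against EV, and within slide 3 for EV and for TNF against control, just 1 of the 2 arrays compared stood apart, so these values mix the treatment with that difference.

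**Figure D1:**
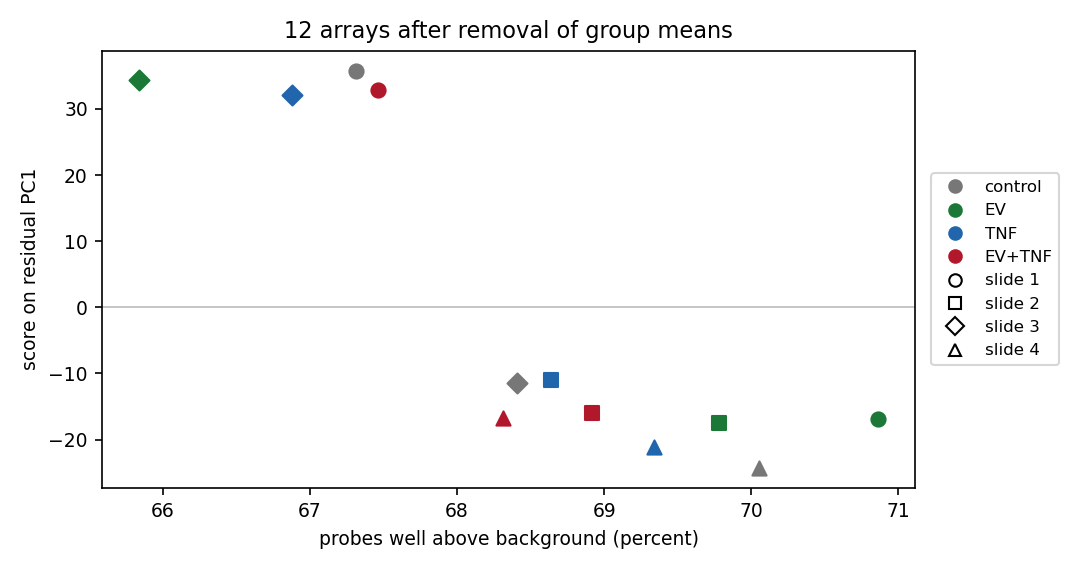
The score of each of the 12 arrays on the first principal component of the residuals from the group means (arbitrary units, vertical axis) is plotted against the percentage of its probes well above background (horizontal axis), with colour for the group and marker shape for the slide. A single array of each group lies at 32.1 to 35.8, on slides 1 and 3, and the other 8 lie at -24.3 to -11.

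TNF alone raised inflammatory chemokines, a matrix protease and genes of the NF-kappaB response. CXCL10, an interferon-inducible chemokine, was 32.8-fold higher than in control cells (log2 fold change 5.03 ± 0.48, SE, n = 3 arrays per group), and MMP9, a gelatinase, was 8.67-fold higher (3.12 ± 0.28). CXCL8 (5.13-fold, 2.36 ± 0.44) and CXCL2 (4.36-fold, 2.12 ± 0.33), which attract neutrophils, and CCL2, which attracts monocytes (2.35-fold, 1.23 ± 0.23), rose as well. The secreted amino acid oxidase IL4I1 rose 4.01-fold (2.00 ± 0.11), the calcium-binding protein CALN1 4.58-fold (2.20 ± 0.26) and the hormone precursor GHRL 9.66-fold (3.27 ± 0.57). CTSS, a lysosomal protease that processes the invariant chain, was 3.65-fold lower (-1.87 ± 0.22), and IGLL1, a part of the pre-B cell receptor, 2.93-fold lower (-1.55 ± 0.28).

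In all, 70 genes were called higher and 14 lower with TNF, 36 and 6 of them by at least 2-fold. The smallest adjusted p was 1.22e-05, for RELB. The arrays of the 2 groups did not overlap for 13.1% of the genes, where chance gives 10%. Further called falls were those of ATP2C2, a calcium pump of the secretory pathway (-1.03 ± 0.13), TXNIP, an inhibitor of thioredoxin (-0.82 ± 0.15), the adhesion protein ICAM4 (-0.74 ± 0.14), the granule protease PRSS57 (-0.77 ± 0.14), PDYN (-0.80 ± 0.14) and MELTF-AS1 (-1.12 ± 0.16). PLXDC2 and MTUS1 were not well above background on any TNF array and were at least 1.86-fold and 1.35-fold lower. MTUS1 had been measured on just 1 control array. With the slide as a block 41 genes were called (32 higher, 9 lower), 35 of them among the 84. With the 4 arrays that stood apart as a block 822 were called. The count was 31 without control replicate 1, 52 without control 3, 43 without EV 1 and 41 without EV 2. It was 38 without EV+TNF 1, 44 without EV+TNF 2, 22 without TNF 1, 55 without TNF 2 and 36 without TNF 3. CXCL10, MMP9, IL4I1, CALN1 and CTSS stayed called whichever of the 12 arrays was left out. CXCL8, CCL2 and IGLL1 lost the call in 10 of 12 such fits, GHRL, PDYN and PRSS57 in 9, CXCL2 and MELTF-AS1 in 4, PLXDC2 in 5, TXNIP in 11, ICAM4 in 12 and ATP2C2 and MTUS1 in 1. Of the genes named with the lists below, TNFRSF21 and CEBPB lost it in 9, SQSTM1 in 5, TRAF3 and HLA-DQA2 in 4 and CYLD and CD74 in 2.

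Of the 38 measured genes of the list NF-kappaB targets and feedback, 7 were called higher with TNF and 0 lower over all genes, and 17 higher and 1 lower adjusted over the list alone. Among them were BIRC3, a ubiquitin ligase that restrains cell death (3.87-fold, 1.95 ± 0.11), RELB, an NF-kappaB subunit (1.76 ± 0.087), TNFAIP3, which ends NF-kappaB signalling (1.71 ± 0.21), and the adhesion protein ICAM1 (1.12 ± 0.14). The list's median log2 fold change was 0.44 (camera adjusted p = 4.04e-17, and adjusted p = 0.13 with an estimated correlation). It was 0.43 with the slide as a block (adjusted p = 1.46e-11), and 0.27 and 0.46 within slides 3 and 4, which held both groups. Of the 10 TNF response genes set in advance, BIRC3, TNFAIP3, ICAM1, CXCL8 and CCL2 were called. NFKBIA (1.37 ± 0.34, adjusted p = 0.135), SOD2 (0.30 ± 0.12, adjusted p = 0.408), TRAF1 (0.43 ± 0.33, adjusted p = 0.716), IL1B (0.50 ± 0.57, adjusted p = 0.822) and TNF itself (0.013 ± 0.22, adjusted p = 0.99) were not.

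Of 16 MHC class II genes, 5 were called higher and 0 lower over all genes, and 10 higher adjusted over the list alone. CIITA, the transactivator of this gene group, rose by 1.27 ± 0.13, CD74, the invariant chain, by 1.07 ± 0.16, and HLA-DRB3 by 0.83 ± 0.14. HLA-DQA1 and HLA-DQA2 were not well above background on any control or EV array and were at least 6.43-fold and 1.86-fold higher with TNF. The list's median was 0.91 (adjusted p = 1.62e-15, and adjusted p = 0.226 with an estimated correlation). It was 0.69 with the slide as a block (adjusted p = 4.85e-09), and 0.34 and 0.87 within slides 3 and 4. Of 29 cytokines and chemokines, 4 were called higher over all genes and 6 adjusted over the list alone. They had a median of 0.20 (adjusted p = 0.00158, and adjusted p = 0.264 with an estimated correlation) that was 0.16 with the slide as a block (adjusted p = 0.0248) and 0.21 and 0.11 within slides 3 and 4. No immediate early and AP-1 gene of 28 was called over all genes, but 5 were higher and 1 lower adjusted over the list alone. The median was 0.47 (adjusted p = 3.71e-06, and adjusted p = 0.506 with an estimated correlation), 0.32 with the slide as a block (adjusted p = 0.00348), and -0.19 within slide 3, where TNF 2 stood apart, and 0.54 within slide 4.

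Smaller shifts with TNF were called for 8 further lists, each lost with an estimated correlation. The unfolded protein and integrated stress response list (33 genes) had a median of 0.21 (adjusted p = 0.000112, and adjusted p = 0.383 with an estimated correlation), with 0 genes called over all genes and 1 adjusted over the list alone. The TNF receptor signalling list (36 genes, median 0.088, and -0.002 with spike-in scaling) had 3 genes called higher and 5 adjusted over the list alone, with an adjusted p = 0.00146, and adjusted p = 0.226 with an estimated correlation. Those 3 were TRAF3 (0.72 ± 0.11), CYLD (0.89 ± 0.13) and TNFRSF21 (0.56 ± 0.097). The first and second are known as brakes on NF-kappaB. MHC class I antigen processing (21 genes) had a median of 0.13 (adjusted p = 0.00309, and adjusted p = 0.144 with an estimated correlation), with 0 called over all genes and 3 adjusted over the list alone. The NRF2 targets (24 genes) had a median of 0.19 (adjusted p = 0.00419, and adjusted p = 0.639 with an estimated correlation), with SQSTM1, an autophagy receptor (0.75 ± 0.12), as the called gene of the list and 2 adjusted over the list alone. The vesicle, endosome and lysosome list (44 genes) had a median of 0.19 (adjusted p = 0.0021, and adjusted p = 0.504 with an estimated correlation), although its called gene was CTSS, which fell. Monocyte differentiation (45 genes, median 0.11, adjusted p = 0.0326, and adjusted p = 0.682 with an estimated correlation) had CEBPB as its called gene and 7 adjusted over the list alone. Adhesion and matrix proteases (32 genes, 0.12, adjusted p = 0.0239, and adjusted p = 0.184 with an estimated correlation) had MMP9 and 2. TGF-beta targets (22 genes, 0.19, adjusted p = 0.0239, and adjusted p = 0.208 with an estimated correlation) had 0 called and 1 adjusted over the list alone.

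With the slide as a block the last 3 of these calls were lost, at medians of 0.037 (adjusted p = 0.355), 0.12 (adjusted p = 0.111) and 0.17 (adjusted p = 0.117). The monocyte call was also lost without control 2 (adjusted p = 0.38), EV 3 (0.0517), TNF 1 (0.106) or TNF 3 (0.154), and the adhesion call without control 1 (0.0685) or TNF 3 (0.0504). Lost in the same way were the TGF-beta call without control 2 (0.122) or TNF 3 (0.129), the NRF2 call without control 3 (0.127) or TNF 2 (0.102), and the vesicle formation, endosome and lysosome call without control 3 (0.0717). The MHC class I call was lost with spike-in scaling (median 0.036, adjusted p = 0.0614).

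All 44 cytosolic ribosomal protein genes lay lower with TNF, with 0 called, and a median of -0.19 (adjusted p = 1.88e-10, and adjusted p = 0.262 with an estimated correlation). It was -0.21 with the slide as a block (adjusted p = 3.09e-09), and -0.21 and -0.26 within slides 3 and 4. With quantile normalization it was -0.041 and the call was lost (adjusted p = 0.0935). The B cell markers (6 of 17 listed genes measured) had a median of -0.34 (adjusted p = 0.00789, and adjusted p = 0.506 with an estimated correlation), with IGLL1 called over all genes and 2 lower adjusted over the list alone. Leaving out control 3 ended the call (adjusted p = 0.0742), as did leaving out TNF 2 (adjusted p = 0.0672). The interferon-stimulated genes (40 genes) were not called as a list (median -0.071, test direction up, adjusted p = 0.819), but 2 of them were called higher, among them IFIH1, a sensor of viral RNA (0.92 ± 0.11). Mitosis (39 genes, median 0.076, adjusted p = 0.127), hypoxia and glycolysis (32 genes, 0.031, adjusted p = 0.381) and cholesterol synthesis (23 genes, 0.048, adjusted p = 0.601) were not called. Neither were apoptosis regulators (30 genes, -0.015 with an upward test, adjusted p = 0.964), p53 targets (21 genes, -0.034 with a mean of 0.051, adjusted p = 0.794) or heat shock genes (19 genes, 0.049 with a mean of -0.008, adjusted p = 0.978). Leaving out control 2 or TNF 1 called the mitosis and G2/M list (adjusted p = 0.00107 and 0.00396). Leaving out control 3 or TNF 2 called the hypoxia and glycolysis list (adjusted p = 0.0264 and 0.0241).

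**Figure D2:**
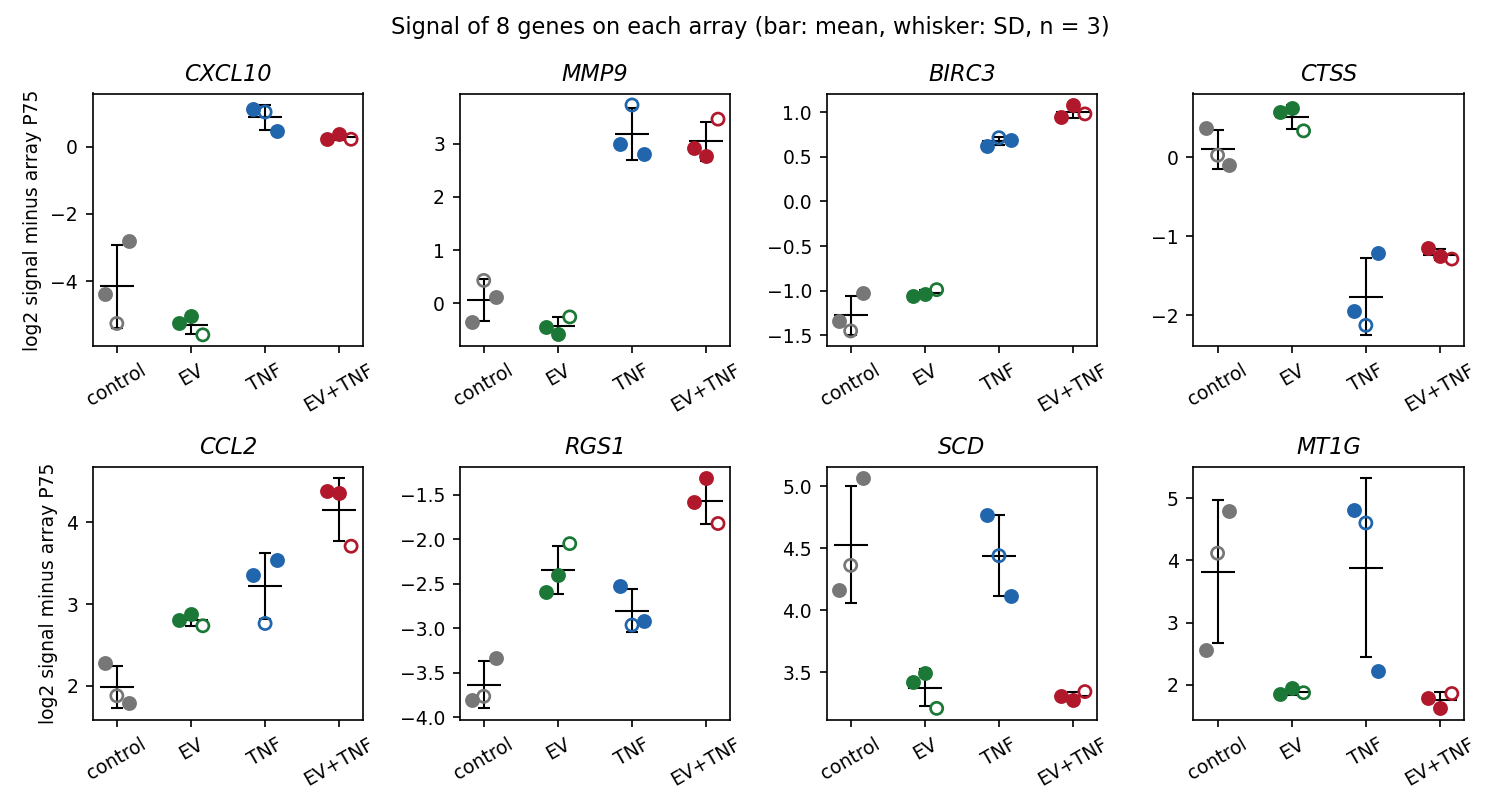
Log2 signal minus the 75th percentile of each array (vertical axis) is shown for CXCL10, MMP9, BIRC3, CTSS, CCL2, RGS1, SCD and MT1G in the control, EV, TNF and EV+TNF groups (horizontal axis), with a point per array, open circles for the 4 arrays that stood apart, a bar at the mean and a whisker of 1 SD (n = 3). CXCL10 lies at -4.16 in control and 0.88 in TNF cells on average, and CCL2 at 1.98, 2.80, 3.22 and 4.15 in the 4 groups in that order.

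In the presence of EVs, TNF raised much the same kind of genes (EV+TNF against EV). CXCL10 was 47.8-fold higher (5.58 ± 0.48, SE, n = 3) and MMP9 11.1-fold (3.48 ± 0.28). BIRC3 (4.09-fold, 2.03 ± 0.11), NFE2L3 (1.92 ± 0.17), the immune cell adhesion protein CD48 (2.70 ± 0.51), SLAMF8 (1.87 ± 0.31), CALN1 (2.10 ± 0.26) and GHRL (3.30 ± 0.57) rose. HLA-DQA1 and HLA-DQA2 were at least 5.34-fold and 1.78-fold higher. CTSS was 3.35-fold lower (-1.74 ± 0.22). IGLL1 (-1.65 ± 0.28), the glutamate receptor GRM8 (-1.76 ± 0.31), LEFTY1 (-1.56 ± 0.24), ATP2C2 (-1.24 ± 0.13), MID1 (-1.12 ± 0.16), PLAC8 (-1.03 ± 0.16) and the potassium channel KCNA3 (-0.98 ± 0.18) fell. SCRN1 and FGF7 were not well above background on any EV+TNF array and were at least 1.53-fold and 2.45-fold lower.

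In this comparison 72 genes were called higher and 31 lower, 36 and 9 of them by at least 2-fold, and 20.7% of the genes had arrays that did not overlap, where chance gives 10%. The split was 88 higher and 63 lower with quantile normalization, and 34 higher and 8420 lower with spike-in scaling, which moved the median of all genes to -0.67. With the slide as a block 145 were called, 73 of them among the 103. The count was 162 without control 1, 27 without EV 1, 22 without EV 2, 283 without EV 3, 19 without EV+TNF 1, 28 without EV+TNF 2 and 55 without TNF 1. CXCL10, MMP9, BIRC3, NFE2L3, CALN1, CTSS, ATP2C2, HLA-DQA1 and SCRN1 stayed called whichever array was left out. CD48 and KCNA3 lost the call in 9 of 12 such fits, HLA-DQA2 in 10, FGF7 in 7, GHRL, SLAMF8 and GRM8 in 6, IGLL1 in 5, LEFTY1 and MID1 in 4 and PLAC8 in 3. Of the genes named with the lists below, ELANE and HLA-DPB1 lost it in 8, CXCL2 in 7, CCL2 and DUSP4 in 5, MS4A3 in 4, CD74 in 3, ICAM1 in 2 and TNFAIP3 in 1.

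Of the NF-kappaB list, 6 genes were called higher and 0 lower, and 15 higher and 1 lower adjusted over the list alone, among them RELB (1.40 ± 0.087), TNFAIP3 (1.61 ± 0.21) and ICAM1 (1.04 ± 0.14). The list's median was 0.34, and -0.32 with spike-in scaling, and it lay above the other genes under both (adjusted p = 3.62e-10 and 1.71e-18, and adjusted p = 0.168 with an estimated correlation). It was 0.30 with the slide as a block (adjusted p = 3.65e-06), and 0.27 and 0.46 within slides 1 and 2, which held both groups. MHC class II genes were called higher in 6 of 16 cases and in 10 adjusted over the list alone, with CIITA (1.45 ± 0.13), CD74 (1.09 ± 0.16) and HLA-DPB1 (1.66 ± 0.30) among them. Their median was 0.89 (adjusted p = 7.63e-14, and adjusted p = 0.231 with an estimated correlation), 0.71 with the slide as a block (adjusted p = 1.33e-07), and 0.32 and 0.86 within slides 1 and 2. Among cytokines, CXCL10, CXCL2 (1.83 ± 0.33) and CCL2 (1.35 ± 0.23) were called higher, and 8 were higher and 1 lower adjusted over the list alone. Their median was 0.26 (-0.40 with spike-in scaling; adjusted p = 0.000224, and adjusted p = 0.226 with an estimated correlation), with -0.064 and 0.34 within slides 1 and 2, the first with EV+TNF 3.

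The granule and progenitor list, which holds genes of immature myeloid cells, had 2 genes called lower, ELANE (-0.65 ± 0.12) and MS4A3 (-0.82 ± 0.13), and 4 lower adjusted over the list alone. Its median was -0.26 (adjusted p = 0.00294, and adjusted p = 0.144 with an estimated correlation), with -0.42 and -0.29 within slides 1 and 2, and the call was lost with spike-in scaling (-0.92, adjusted p = 0.0673). The AP-1 list had DUSP4 called higher (0.55 ± 0.085; -0.11 with spike-in scaling), and 5 higher adjusted over the list alone. Its median was 0.31 (-0.35 with spike-in scaling; adjusted p = 0.000226, and adjusted p = 0.608 with an estimated correlation), with -0.11 within slide 1, where EV+TNF 3 stood apart, and 0.56 within slide 2. The stress response list had 0 called genes and a median of 0.18 (-0.48 with spike-in scaling; adjusted p = 0.00339, and adjusted p = 0.507 with an estimated correlation). DNA replication genes (40 genes) had 0 called and a median of -0.095 (adjusted p = 0.0219, and adjusted p = 0.626 with an estimated correlation). That call was lost without EV 1 (adjusted p = 0.094), EV 2 (0.0823) or EV+TNF 3 (0.412). MHC class I, adhesion, monocyte, TGF-beta and B cell lists were called at medians of 0.057, 0.088, 0.13, 0.17 and -0.32 (adjusted p = 0.0317, 0.0341, 0.0493, 0.0133 and 0.0454), and adjusted p = 0.214, 0.211, 0.698, 0.168 and 0.612 with an estimated correlation. With spike-in scaling the medians of the first 4 were -0.60, -0.57, -0.53 and -0.49, and the MHC class I and B cell calls were lost (adjusted p = 0.949 and 0.363). Quantile normalization ended the MHC class I, monocyte and B cell calls (0.06, 0.0641 and 0.058), and scaling on the median those of the adhesion, monocyte and DNA replication lists (0.0713, 0.0607 and 0.0769). With the slide as a block the calls of the same 4 lists were lost (adjusted p = 0.14, 0.0849, 0.466 and 0.0849). All 4 and the B cell call were lost in at least 1 fit without an array. For MHC class I this was so without EV 3 (0.172) or EV+TNF 3 (0.0688), for adhesion without EV 3 (0.182), EV+TNF 1 (0.0624) or EV+TNF 2 (0.131) and for TGF-beta without EV 3 (0.0517). Monocyte genes lost it without control 1 (0.0732), control 2 (0.0525), control 3 (0.051), EV 3 (0.795), EV+TNF 1 (0.333) or EV+TNF 2 (0.152). B cell genes lost it without control 1 (0.0669), control 2 (0.0515), control 3 (0.0527), EV 1 (0.107), EV 2 (0.0868), EV+TNF 3 (0.195) or TNF 3 (0.0504).

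With both treatments (EV+TNF against control), chemokines such as CXCL10 and the protease MMP9 rose. CXCL10 was 21.6-fold higher (4.43 ± 0.48, SE, n = 3), CXCL2 8.40-fold (3.07 ± 0.33), MMP9 7.92-fold (2.99 ± 0.28), CXCL8 7.22-fold (2.85 ± 0.44) and CCL2 4.49-fold (2.17 ± 0.23). CXCL11 (2.38 ± 0.53), CXCL3 (2.15 ± 0.31), the metalloprotease ADAMDEC1 (2.53 ± 0.47) and GHRL (3.19 ± 0.57) rose too. HLA-DQA1 and HLA-DQA2 were at least 4.95-fold and 1.65-fold higher. IGLL1 was 3.94-fold lower (-1.98 ± 0.28). KRT77 (-1.95 ± 0.41), the kinase anchor AKAP7 (-1.81 ± 0.23), ANXA2R (-1.71 ± 0.38), the kinase BMX (-1.68 ± 0.25), CREG2 (-1.38 ± 0.18) and ATP2C2 (-1.37 ± 0.13) fell. SCRN1, KLHL4 and ACSL6 were not well above background on any EV+TNF array and were at least 1.22-fold, 2.45-fold and 2.52-fold lower.

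This comparison called 157 genes higher and 109 lower, 58 and 28 of them by at least 2-fold, and 18.2% of genes had arrays that did not overlap, where chance gives 10%. Spike-in scaling called 26 higher and 35 lower. The slide as a block left 124 called (83 higher, 41 lower), 116 of them among the 266. The count was 85 without control 3, 155 without EV 1, 158 without EV 2, 66 without EV+TNF 1, 63 without EV+TNF 2, 159 without EV+TNF 3 and 154 without TNF 1. CXCL10, CXCL2, CXCL3, MMP9, CCL2, IGLL1, AKAP7, CREG2 and ATP2C2 stayed called whichever array was left out. CXCL8 and GHRL lost the call without EV+TNF 1 or EV+TNF 2, BMX without EV+TNF 1, ADAMDEC1 in 5 of 12 such fits, KRT77 in 9, ANXA2R in 10, ACSL6 in 6, HLA-DQA2 in 2 and CXCL11 in 11. Of the genes named with the lists below, MS4A3 lost it in 11, CD82 and EBF1 in 9, TGFBR1, SKIL and DUSP4 in 8 and PPP1R15A in 7. SCD and SPRY2 lost it in 4, SREBF1, ELANE, SERPINB1, DDIT3 and NPC1 in 3 and EGR2 and CTSS in 2.

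The NF-kappaB list had 9 genes called higher and 0 lower, and 20 higher and 1 lower adjusted over the list alone, led by BIRC3 (4.86-fold, 2.28 ± 0.11). Its median was 0.49 (adjusted p = 4.85e-17, and adjusted p = 0.13 with an estimated correlation), with 0.47 within each of slides 1 and 4, which held both groups. MHC class II had 6 genes called higher and 10 adjusted over the list alone. They had a median of 0.93 (adjusted p = 1.56e-13, and adjusted p = 0.236 with an estimated correlation), and 1.00 and 0.92 within slides 1 and 4. Cytokines had 6 called higher and 6 adjusted over the list alone, with a median of 0.27 (adjusted p = 1.08e-05, and adjusted p = 0.184 with an estimated correlation). The monocyte list had 4 called higher, among them the scavenger receptor CD36 (1.27 ± 0.15), CEBPB (0.87 ± 0.10) and EGR2 (2.22 ± 0.34), which drive or mark monocyte maturation, and 7 adjusted over the list alone. Its median was 0.15, and -0.094 with spike-in scaling (adjusted p = 0.0018, and adjusted p = 0.506 with an estimated correlation). Without control 2 the call was lost (adjusted p = 0.0543). The granule list had 3 called lower, the proteases and protease inhibitor ELANE (-0.75 ± 0.12) and SERPINB1 (-0.54 ± 0.091) and the progenitor protein MS4A3 (-0.59 ± 0.13), and 5 adjusted over the list alone. Their median was -0.38 (adjusted p = 0.000112, and adjusted p = 0.13 with an estimated correlation), -0.39 with the slide as a block (adjusted p = 7.23e-05), and -0.43 and -0.27 within slides 1 and 4.

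The LXR and lipid list (17 genes) had 2 called lower, SREBF1, a regulator of lipid synthesis (-0.55 ± 0.091), and SCD, a fatty acid desaturase (-1.22 ± 0.22; 1 of its 2 other probes went the opposite way). Its median was -0.14 (adjusted p = 0.0493, and adjusted p = 0.231 with an estimated correlation). That call was lost with the slide as a block (median -0.17, adjusted p = 0.0587), with spike-in scaling (-0.38, adjusted p = 0.1) and with quantile normalization (-0.13, adjusted p = 0.0517). It was also lost without control 1 (0.0731), control 3 (0.0984), EV 1 (0.0526), EV 2 (0.0514), EV 3 (0.0517), EV+TNF 2 (0.0543), EV+TNF 3 (0.0881), TNF 2 (0.0616) or TNF 3 (0.0643). The TGF-beta list had TGFBR1 (0.87 ± 0.17) and SKIL (0.72 ± 0.15) called higher, 2 adjusted over the list alone and a median of 0.30 (adjusted p = 0.000668, and adjusted p = 0.13 with an estimated correlation). The AP-1 list had SPRY2 (0.88 ± 0.16) and DUSP4 (0.44 ± 0.085), which damp growth factor signals, called higher, and 8 higher and 1 lower adjusted over the list alone. Its median was 0.39 (adjusted p = 1.06e-05, and adjusted p = 0.507 with an estimated correlation). The vesicle list had the lysosomal cholesterol carrier NPC1 (1.02 ± 0.17) and the tetraspanin CD82 (1.04 ± 0.22) called higher and CTSS lower (-1.33 ± 0.22). Adjusted over the list alone, 6 were higher and 1 lower, and the median was 0.15 (-0.097 with spike-in scaling; adjusted p = 0.000413, and adjusted p = 0.383 with an estimated correlation). The stress response list had DDIT3 (0.94 ± 0.17) and PPP1R15A (1.00 ± 0.19) called higher, and 2 adjusted over the list alone. Its median was 0.19 (-0.059 with spike-in scaling; adjusted p = 0.0021, and adjusted p = 0.506 with an estimated correlation), a call lost without control 1 (adjusted p = 0.107). Adhesion (2 called higher, median 0.18, -0.068 with spike-in scaling) and TNF receptor signalling (3 called higher, median 0.098, -0.15 with spike-in scaling) had adjusted p = 0.0169 and 0.0023, and adjusted p = 0.168 and 0.231 with an estimated correlation. The former was lost without control 1 (0.0936) or EV+TNF 2 (0.0552). The B cell list had IGLL1 and EBF1 called lower (median -0.47, adjusted p = 0.00362, and adjusted p = 0.461 with an estimated correlation). The ribosomal proteins lay lower in 43 of 44 cases (median -0.13, adjusted p = 0.0021, and adjusted p = 0.612 with an estimated correlation), lost without control 1 (adjusted p = 0.0948) and with quantile normalization (-0.021, adjusted p = 0.748). The nuclear genes of the respiratory chain lay lower in 34 of 38 cases (median -0.095, adjusted p = 0.0155, and adjusted p = 0.698 with an estimated correlation). This was lost without control 2 (0.206) or EV+TNF 1 (0.0694) and with the slide as a block (-0.074, adjusted p = 0.0851), quantile normalization (-0.031, adjusted p = 0.202) or scaling on the median (-0.088, adjusted p = 0.182).

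EVs alone changed no single gene past the adjusted threshold (EV against control). With limma, 0 genes were called higher and 0 lower, 2200 genes had an unadjusted p under 0.05 where 662 would be expected by chance, and the smallest adjusted p was 0.0606. The 5 genes with the smallest p all had adjusted p = 0.0606, among them CAB39L, a scaffold of the kinase LKB1 (log2 difference 0.80 ± 0.10, SE, n = 3), FNIP2 (0.87 ± 0.12), SLC27A5 (-0.75 ± 0.095) and the transcription factor NKX2-1 (-1.23 ± 0.17). The arrays of the groups did not overlap for 18.1% of genes, where chance gives 10%. The call of 0 genes rested on single arrays and on the treatment of the slide. Without control 1, 651 genes were called, and 6 without EV 3. There were 163 with the slide as a fixed block (67 higher, 96 lower) and 1896 with the 4 arrays that stood apart as a block. No other software was used for this test.

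The NF-kappaB list lay higher with EVs alone, with 0 genes called over all genes and 4 higher adjusted over the list alone: NFKBIB (0.87 ± 0.24), RELB (0.32 ± 0.087), the survival gene BCL2A1 (0.38 ± 0.099) and IRF1 (0.41 ± 0.11). Its median was 0.15 (adjusted p = 0.00643, and adjusted p = 0.506 with an estimated correlation). It was 0.15 with the slide as a block (adjusted p = 0.016), and 0.36 and 0.057 within slides 1 and 3, where 1 array of each pair stood apart. Leaving out control 2 ended the call (adjusted p = 0.0612), as did spike-in scaling (0.57, adjusted p = 0.0691). The LXR list had 3 genes lower adjusted over the list alone, SREBF1 (-0.43 ± 0.091), SCD (-1.15 ± 0.22) and the fatty acid oxidation enzyme ACADVL (-0.47 ± 0.10). Its median was -0.16 (adjusted p = 0.0493, and adjusted p = 0.231 with an estimated correlation). With spike-in scaling, which moved the median of all genes to 0.40, it was 0.25 (adjusted p = 0.0103). Within slides 1 and 3 it was -0.091 and -0.53, and its call was lost with the slide as a block (median -0.16, adjusted p = 0.0614). It was also lost without control 1 (0.105), control 3 (0.0966), EV 3 (0.201), EV+TNF 1 (0.0594), EV+TNF 2 (0.05), TNF 2 (0.0619) or TNF 3 (0.0593). DNA replication genes lay higher in 32 of 40 cases (median 0.11, adjusted p = 0.0108, and adjusted p = 0.596 with an estimated correlation). Without control 2 this was lost (adjusted p = 0.0672). Respiratory chain genes lay lower in 31 of 38 cases (median -0.13, adjusted p = 0.00294, and adjusted p = 0.619 with an estimated correlation). The call was lost with spike-in scaling (0.28, adjusted p = 0.363) and with quantile normalization (-0.051, adjusted p = 0.118). They lay at -0.28 and -0.006 within slides 1 and 3. It was also lost without control 2 (0.0537), and NDUFA2 was lower adjusted over the list alone (-0.44 ± 0.088). Ribosomal proteins lay lower in 37 of 44 cases (median -0.12, adjusted p = 0.0118, and adjusted p = 0.695 with an estimated correlation). The call was lost with spike-in scaling (0.29, adjusted p = 0.939) and with quantile normalization (-0.004, adjusted p = 0.965). They lay at 0.001 and -0.085 within slides 1 and 3, with a call lost without control 1 (0.283) or EV 3 (0.17).

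Other lists were not called with EVs alone. The cytokines had 3 genes higher adjusted over the list alone, CXCL2 (1.24 ± 0.33), CCL1 (0.90 ± 0.25) and CCL2 (0.82 ± 0.23), with a list median of 0.13 (adjusted p = 0.343). The vesicle list had 4 higher and 3 lower adjusted over the list alone, among them NPC1 (0.77 ± 0.17), ATP6V1H, a part of the lysosomal proton pump (0.65 ± 0.13), and FLOT1 (-0.89 ± 0.15), with a median of 0.14 (adjusted p = 0.0697). Leaving out control 2, EV 1 or EV 2 called the vesicle formation, endosome and lysosome list (adjusted p = 0.00728, 0.0381 and 0.0432). The T cell markers, of the cell type of the EV source line (14 of 37 listed genes measured), had 2 genes lower adjusted over the list alone, RAG1 (-1.11 ± 0.25) and PRKCQ (-1.09 ± 0.25), and a median of -0.073 (adjusted p = 0.342). The p53 targets had ZMAT3 (1.007 ± 0.28) and RRM2B (0.72 ± 0.19) higher adjusted over the list alone and a median of 0.14 (adjusted p = 0.0751).

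Added to TNF, EVs again changed no single gene past the threshold (EV+TNF against TNF). With limma, 0 genes were called higher and 0 lower, 1068 had an unadjusted p under 0.05 (662 expected), and 15.3% had arrays that did not overlap, where chance gives 10%. The smallest p belonged to CYP1A1, an enzyme induced through the aryl hydrocarbon receptor (1.96-fold higher, 0.97 ± 0.12, SE, n = 3, adjusted p = 0.0672), and MTUS1 (adjusted p = 0.0672), which was not well above background on any TNF array and was at least 1.53-fold higher. KLHL29 (1.33 ± 0.19, adjusted p = 0.101), RGS1, which shortens signals of G protein coupled receptors (1.23 ± 0.20, adjusted p = 0.221), and ME1 (at least 1.55-fold lower, adjusted p = 0.221) followed. KLHL29 was the single gene called without control 2, and 9 genes were called with the 4 arrays that stood apart as a block. None of the 10 TNF response genes was called, with NFKBIA at -0.090 ± 0.34, TNFAIP3 at 0.057 ± 0.21, ICAM1 at 0.059 ± 0.14, BIRC3 at 0.33 ± 0.11, CCL2 at 0.93 ± 0.23, CXCL8 at 0.49 ± 0.44 and TNF at 0.46 ± 0.22, and adjusted p = 0.424 or above.

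The granule list lay lower with EVs on top of TNF in 15 of 19 cases, with 0 genes called and 0 adjusted over the list alone (median -0.23, adjusted p = 0.00251, and adjusted p = 0.144 with an estimated correlation). Its median was -0.25 with the slide as a block (adjusted p = 0.00221) and -0.21 and -0.15 within slides 2 and 4. The LXR list lay lower, with 3 genes lower adjusted over the list alone, SREBF1 (-0.50 ± 0.091), SCD (-1.13 ± 0.22) and ACADVL (-0.34 ± 0.10). Its median was -0.18 (adjusted p = 0.0246, and adjusted p = 0.211 with an estimated correlation). It was -0.20 with the slide as a block (adjusted p = 0.0336) and -0.25 and -0.17 within slides 2 and 4. Its call was lost without EV+TNF 3 (0.0696) or TNF 3 (0.082), with spike-in scaling (-0.33, adjusted p = 0.0534) and with quantile normalization (-0.13, adjusted p = 0.0515). Respiratory chain genes lay lower in 34 of 38 cases, with 0 called (median -0.13, adjusted p = 0.000766, and adjusted p = 0.567 with an estimated correlation). They lay at -0.11 with the slide as a block (adjusted p = 0.00168) and -0.17 and -0.055 within slides 2 and 4, and the call was lost without TNF 2 (0.0514). Cytokines lay higher (median 0.15, and -0.012 with spike-in scaling; adjusted p = 0.0285, and adjusted p = 0.506 with an estimated correlation), with 0 called and 0 adjusted over the list alone. The median was 0.10 with the slide as a block (adjusted p = 0.0154) and 0.092 and 0.021 within slides 2 and 4. This call was lost without EV+TNF 1 (0.182), EV+TNF 2 (0.0819) or TNF 2 (0.38). Ribosomal proteins lay higher in 34 of 44 cases (median 0.073, adjusted p = 0.00339, and adjusted p = 0.629 with an estimated correlation). The call was lost with spike-in scaling (-0.084, adjusted p = 0.179), scaling on the median (-0.002, adjusted p = 0.0977) and quantile normalization (0.032, adjusted p = 0.202). They lay at 0.038 and 0 within slides 2 and 4, and the call was also lost without EV+TNF 1 (0.0506), TNF 2 (0.105) or TNF 3 (0.0593).

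Averaged over both levels of TNF (the EV main effect), the genes called included RGS1, 3 chemokines, 3 genes of lipid metabolism and 3 of 11 metallothioneins. RGS1 was 2.40-fold higher (1.26 ± 0.14, SE, n = 6 arrays per level), the complexin CPLX3 8.25-fold (3.05 ± 0.54), and the chemokines CXCL2 (1.095 ± 0.23), CCL2 (0.88 ± 0.17) and CCL1 (0.79 ± 0.17) rose. SCD was 2.21-fold lower (-1.14 ± 0.16), SREBF1 fell by 0.47 ± 0.064 and ACADVL by 0.40 ± 0.070. The metal-binding metallothioneins MT1B (-2.29 ± 0.40), MT2A (-2.08 ± 0.49) and MT1G (-2.03 ± 0.47) fell, but the 2 arrays without EVs on slide 4 lay closer to the EV arrays for this gene family. UQCC3, which helps assemble respiratory complex III, was 4.51-fold lower (-2.17 ± 0.29).

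In the EV main effect 228 genes were called higher and 288 lower, 28 and 38 of them by at least 2-fold, with a smallest adjusted p of 0.009. The split was 9 higher and 4 lower with scaling on the median and 64 higher and 8 lower with spike-in scaling. Further named rises, chosen by the extended rule, were SCG3 (1.82 ± 0.34), the ceramide-forming enzyme SMPD3 (1.43 ± 0.31), the transcription factor DMBX1 (1.35 ± 0.16), and, measured on part of the arrays, MGAT3 (1.48 ± 0.27, on 9 of 12), ANO1 (at least 1.55-fold, on 4), SPOCD1, MTUS1 and GPR34. No difference is given for the last 3, because SPOCD1 and MTUS1 were not well above background on any TNF array and GPR34 was not on any control array. Further falls were IFT46 (-1.65 ± 0.33), the dynein light chain DYNLL1 (-1.59 ± 0.31), ZNF619 (-1.55 ± 0.24), the protease PCSK5 (-1.38 ± 0.29), FJX1 (-1.37 ± 0.30) and the thrombin receptor F2R (-1.40 ± 0.34, on 9 arrays). The count was 563 with the slide as a block, of which 362 were among the 516, and 3145 with the 4 arrays that stood apart as a block. It was 1272 without control 1, 49 without control 2, 50 without control 3, 13 without EV 1, and 10 without EV 2. It was 6 without EV+TNF 1, 26 without EV+TNF 2, 33 without EV+TNF 3, 10 without TNF 1 and 82 without TNF 2. The genes that stayed called whichever array was left out numbered 6, among them RGS1, CAB39L, CYP1A1, RBMS3 and SLC27A5, of which those other than RGS1 were named after their values were seen. SCD and UQCC3 lost the call in 4 of 12 such fits, SREBF1 in 5, ACADVL and CCL2 in 8, CPLX3, CXCL2 and MT1B in 9, and MT2A, MT1G and CCL1 in 10. SCG3, SMPD3, SPOCD1, ANO1, IFT46, DYNLL1, PCSK5, FJX1 and F2R lost it in 9, GPR34 in 10, MGAT3 in 8, ZNF619 in 7, MTUS1 in 2 and DMBX1 in 1. Of the genes named with the lists below, ATP6V1H and RAG1 lost it in 10, VPS4A, PRKCQ, NDUFA1 and NDUFA2 in 9, BCL2A1 in 8, FLOT1 in 7 and NPC1 in 5.

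The LXR list had 3 genes called lower over all genes, those named above, and 4 adjusted over the list alone, with a median of -0.21 (adjusted p = 0.0326, and adjusted p = 0.226 with an estimated correlation) and -0.22 with the slide as a block (adjusted p = 0.0445). Its call was lost without control 1 (0.069), EV 3 (0.0933), EV+TNF 3 (0.051) or TNF 3 (0.0601). Respiratory chain genes lay lower in 35 of 38 cases, with 2 called lower, NDUFA1 (-0.34 ± 0.071) and NDUFA2 (-0.34 ± 0.062). They had a median of -0.13 that was 0.004 with spike-in scaling (adjusted p = 0.000413, and adjusted p = 0.54 with an estimated correlation) and -0.13 with the slide as a block (adjusted p = 0.000667). The granule list (median -0.18, adjusted p = 0.0302, and adjusted p = 0.214 with an estimated correlation) and the NF-kappaB list (median 0.093, adjusted p = 0.0337, and adjusted p = 0.612 with an estimated correlation) had 0 and 1 called genes, the latter BCL2A1 (0.40 ± 0.070). There were 2 lower and 4 higher adjusted over the list alone. They were -0.20 and 0.095 with the slide as a block (adjusted p = 0.0359 and 0.0406). Quantile normalization ended the granule call (-0.16, adjusted p = 0.119) and spike-in scaling the NF-kappaB call (0.22, adjusted p = 0.0706). The former was lost without control 1 (0.0652), control 3 (0.0527), EV 3 (0.0904), EV+TNF 3 (0.0644) or TNF 3 (0.0504), and the latter without control 1 (0.0596), control 2 (0.0928), EV 1 (0.052), EV 2 (0.0567), EV+TNF 1 (0.115), EV+TNF 2 (0.0968), TNF 2 (0.149) or TNF 3 (0.0504). The vesicle list was not called (median 0.085, adjusted p = 0.0695), but NPC1 (0.80 ± 0.12) and ATP6V1H (0.45 ± 0.092) were called higher and FLOT1 (-0.65 ± 0.10) and VPS4A (-0.96 ± 0.20), which act in vesicle formation, lower. In all 9 were higher and 6 lower adjusted over the list alone. The T cell markers were not called (median -0.011, adjusted p = 0.297), with PRKCQ (-1.002 ± 0.18) and RAG1 (-0.75 ± 0.18) called lower.

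**Figure D3:**
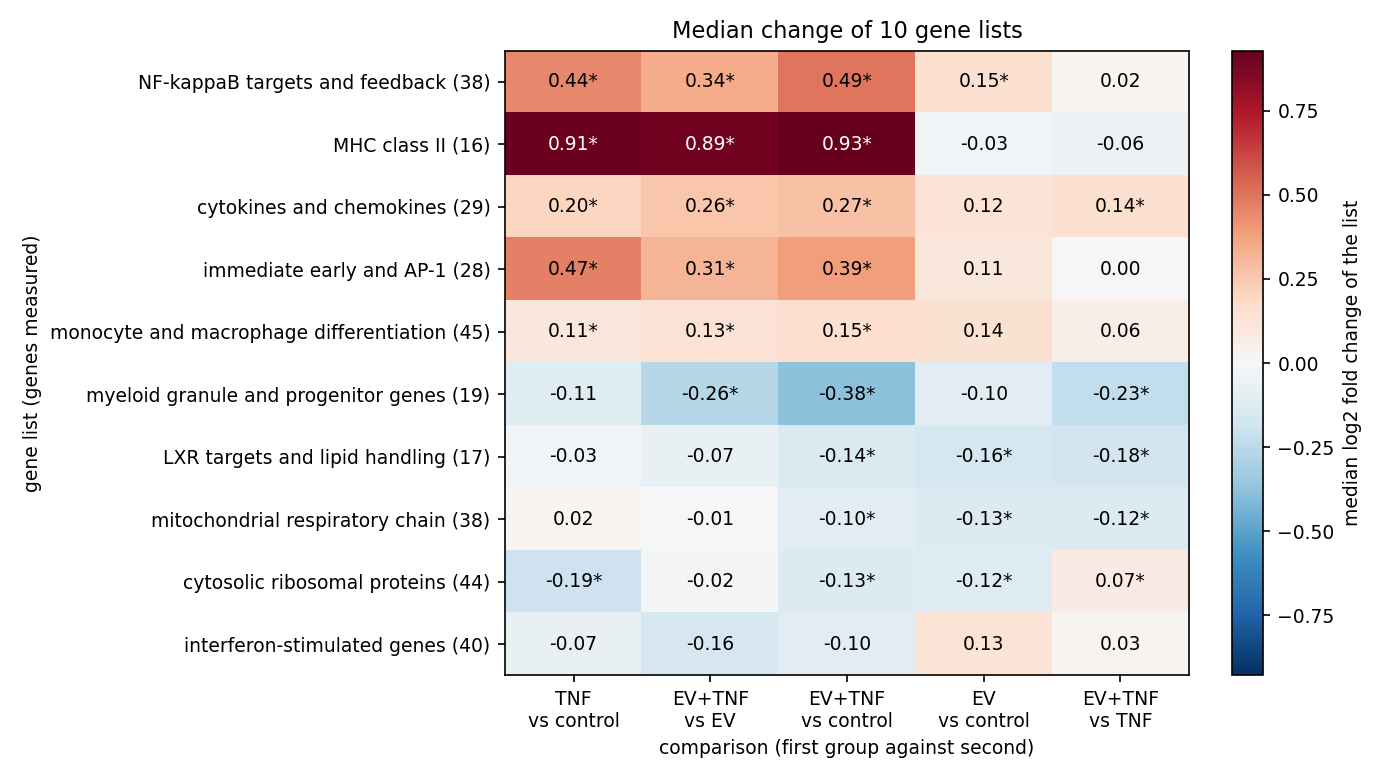
Median log2 fold change of 10 gene lists (rows, with the number of genes measured in brackets) is shown by colour and printed for each of the 5 comparisons of single groups (columns), and a star marks an adjusted p under 0.05 with the preset correlation, of which none held with an estimated correlation. MHC class II lies at 0.91, 0.93 and 0.89 in the 3 comparisons that add TNF, and NF-kappaB at 0.44, 0.49 and 0.34; with spike-in scaling the last of these was -0.32.

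Averaged over both levels of EVs (the TNF main effect), 298 genes were called higher and 255 lower, 57 and 21 of them by at least 2-fold. CXCL10 was 39.6-fold higher (5.31 ± 0.34, SE, n = 6), MMP9 9.82-fold (3.30 ± 0.20), the complement component C3 6.04-fold (2.59 ± 0.48) and CXCL11 5.25-fold (2.39 ± 0.37). NFKBIA, the main inhibitor of NF-kappaB, was called (1.34 ± 0.24, adjusted p = 0.0119). CTSS (-1.81 ± 0.15), IGLL1 (-1.60 ± 0.20), GRM8 (-1.66 ± 0.22) and the mast cell receptor chain MS4A2 (-1.49 ± 0.28) fell. GHRL (3.29 ± 0.41), ADAMDEC1 (2.34 ± 0.33), CD48 (2.32 ± 0.36) and CALN1 (2.15 ± 0.18) rose, and SHC4 (-1.62 ± 0.39), CFAP53 (-1.27 ± 0.22) and AGBL2 (-1.24 ± 0.28) fell as well. PLXDC2, AOX1 and SCRN1 were at least 2.08-fold, 1.68-fold and 1.45-fold lower, AOX1 and SCRN1 having been measured on 5 and 4 arrays. The NF-kappaB list had 16 genes called higher and 0 lower, and 18 higher and 1 lower adjusted over the list alone (median 0.39, adjusted p = 2.48e-14, and adjusted p = 0.144 with an estimated correlation). MHC class II had 10 of 16 called higher and 13 adjusted over the list alone (median 0.90, adjusted p = 3.88e-15, and adjusted p = 0.226 with an estimated correlation). In all 15 lists were called, 0 with an estimated correlation. The monocyte call was lost without control 2 (0.158), EV 3 (0.345), EV+TNF 1 (0.117), EV+TNF 2 (0.0548), TNF 1 (0.0531) or TNF 3 (0.0601), the NRF2 call without control 1 (0.0976), control 3 (0.243), EV 1 (0.0705), EV 2 (0.0661), EV 3 (0.0585), EV+TNF 3 (0.167) or TNF 2 (0.187), and the adhesion call without EV 3 (0.0736). With the slide as a block the monocyte (median 0.043, adjusted p = 0.415), adhesion (0.089, adjusted p = 0.0839) and TGF-beta (0.17, adjusted p = 0.0758) calls were lost. Spike-in scaling ended the MHC class I, granule and B cell calls (0.397, 0.0752 and 0.1), quantile normalization the ribosomal call (0.233) and scaling on the median the NRF2 call (0.0903). The split of the called genes was 75 higher and 4683 lower with spike-in scaling. Under it the median of all genes was -0.39, the NF-kappaB median was 0.019 and 9 list medians turned below 0. These were the cytokine (-0.20), MHC class I (-0.26), monocyte (-0.24), adhesion (-0.28), TNF receptor (-0.31), stress response (-0.21), NRF2 (-0.30), TGF-beta (-0.21) and vesicle (-0.26) lists. The count was 788 with the slide as a block, 441 of them among the 553. It was 349 without control 1, 237 without EV 1, 234 without EV 2, 838 without EV 3, 238 without EV+TNF 1, 276 without EV+TNF 2 and 249 without TNF 1. Whichever array was left out, 216 genes stayed called. SHC4 lost the call in 11 of 12 such fits, AGBL2 in 9, MS4A2 in 3 and C3 in 1.

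Whether EVs acted differently with and without TNF was tested as the interaction. With limma, 0 genes were called, 321 had an unadjusted p under 0.05 where 662 would be expected by chance, and every adjusted p of the named genes was 1. The smallest p belonged to ME1, which makes NADPH, SCRN1, TAF7L, FGF7 and IGFBP3 (log2 difference 0.73 ± 0.16, SE). No difference is given for the first 4, which were not well above background on any array of at least 1 group: ME1 in control and EV+TNF, SCRN1 in TNF and EV+TNF, TAF7L in control and FGF7 in EV+TNF. The 4 lists called in the interaction were the ribosomal proteins (median 0.20, adjusted p = 8.75e-10, and adjusted p = 0.264 with an estimated correlation), DNA replication (-0.12, adjusted p = 0.00938, and adjusted p = 0.584), NF-kappaB (-0.15, adjusted p = 0.0181, and adjusted p = 0.566) and the erythroid and megakaryocyte markers (8 of 17 listed genes measured, 0.25, adjusted p = 0.0277, and adjusted p = 0.506), the latter of each pair with an estimated correlation. With spike-in scaling the medians of the ribosomal and erythroid lists were -0.37 and -0.32, where the median of all genes was -0.59, and the ribosomal and NF-kappaB calls were lost (adjusted p = 0.149 and 0.311). Quantile normalization lowered the ribosomal median to 0.042 (adjusted p = 0.237), and it ended the NF-kappaB (0.0791) and erythroid (0.142) calls. The erythroid call was lost with the slide as a block (median 0.14, adjusted p = 0.212) and without control 1 (0.358), EV 3 (0.235), EV+TNF 1 (0.0662), TNF 1 (0.101) or TNF 2 (0.0993). The NF-kappaB call was lost without control 2 (0.193), EV 1 (0.0705), EV 2 (0.0621), EV+TNF 3 (0.602), TNF 1 (0.261) or TNF 3 (0.0601). The DNA replication call was lost without control 2 (0.112), control 3 (0.0829), EV 1 (0.0729), EV 2 (0.0661), EV+TNF 3 (0.333) or TNF 3 (0.128).

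Across the 13238 genes, the change with EVs alone and the change with EVs on top of TNF correlated with a Pearson r of 0.624 (Spearman 0.582), and 70.7% of the genes had the same sign. With no filter on dim probes this r was 0.26. These comparisons share no arrays, and genes are not independent replicates. The change with TNF was alike in the same way without and with EVs (r = 0.642, Spearman 0.546, and r = 0.314 with no filter): 83 of the 84 genes called with TNF alone had the same sign in EV+TNF against EV. In both, 50 genes were called higher and 6 lower, where independent lists would share 0.381 and 0.0328. EV against control and TNF against control share the control arrays, which alone gave r = 0.5 and a covariance of 0.034 in 100 simulations, and the observed values were 0.0475 and 0.00489. That r was 0.297 with no filter, 0.03 with normexp, 0.0281 with the filter on all arrays and 0.0232 without the 4 arrays that stood apart. The EV and TNF main effects correlated at -0.26, a value that 29 of 99 random relabellings of the arrays reached or went below. Over those relabellings this r ran from -0.759 to 0.708. The r of 0.624 and of 0.642 have no such range beside them, so how they compare with relabelled arrays is not known.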

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

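The tests on slide, replicate number, T cell RNA, the spike-ins and the level of the matched genes, and the search for calls among probes without a gene, were chosen after the result was seen, and those on weaker signal, array scaling and the ribosomal proteins before. The interaction test picked out 4 lists because their change with EVs differed with and without TNF: NF-kappaB targets (median log2 difference -0.15), DNA replication (-0.12), erythroid and megakaryocyte markers (0.25) and ribosomal proteins (0.20). None kept its call with an estimated correlation (adjusted p = 0.264 or above), and no gene was called. The spike-in probes, which no comparison uses, averaged 0.43 (log2) over the 75th percentile in EV+TNF and 0.18 in control. Of 7661 probes that name no gene, 24 were called in the TNF main effect, 14 higher and 10 lower.

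The first pattern weighed was the 4 arrays that stood apart, 1 in each group. Against the slide as the whole cause, 2 arrays of the same slide lay 52.6 apart on the first residual component, and against the replicate number, 2 arrays of the same number lay 55.5 apart, where the other 8 arrays spanned 13.3. Weaker signal near background would leave the brightest genes alike, but over the 4413 brightest genes the gap was 17.4, against a range of 5.89 among the 8 arrays. No biological explanation was tested, because the labels name nothing that these arrays share. A difference in culture or RNA handling stays open and may have added to it.

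The second pattern was the 516 genes called in the EV main effect. Array scaling stays open for the falls. With spike-in scaling 0 of the 288 genes called lower changed sign, but none could, its shift (0.13) being under their smallest fall (0.26). Then 8 were called lower, but rises lost calls too, so the loss was not specific to falls. T cell RNA carried in with the EVs stays open for the falls, as its test could not decide. It took genes already called lower, so their median of -0.567 (SD 0.333) had to lie under the -0.015 of all genes. For the 228 rises such RNA cannot be told apart from a response: the T cell list had a median of 0.0242 without a filter, with members in both directions, and 13 of its 35 members, among them CD3D, CD247, LCK and CD28, were below background on all 12 arrays. An effect of EVs on the cells stays open as a hypothesis, and the count rested on single arrays, with 6 calls without EV+TNF 1.

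The third pattern was the ribosomal protein list in the interaction. Without the 4 arrays that stood apart the median was 0.141, against 0.20 with them, so these arrays were not its whole cause. The brightness of the probes stays open: the list lay at percentile 100 of 10000 random lists matched on expression (medians from -0.026 to 0.087), but its genes were brighter than the matched ones (mean 7.03 against 5.41, log2), and quantile normalization left a median of 0.042 (adjusted p = 0.237). With spike-in scaling the list lay at -0.37, above the median of all genes at -0.59, but was no longer called (adjusted p = 0.149). A biological difference in how EVs act with TNF may also be present and was not tested further.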

How the results depend on the processing

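Spike-in scaling, both treatments of the 4 arrays apart and normexp with a limit on local background were chosen after the data were seen, the rest before. Normexp was planned without that limit and on the mean signal, which the files lack. Of 304 values of named genes, 161 to 297 kept direction and side of the threshold in the settings run on all of them: 161 without EV+TNF 1, 162 with spike-in scaling and 297 with the slide as a random block. Fits without an array made 22 to 138 of them weaker. Of the 74 list calls, 58 were kept with quantile normalization and 58 with spike-in scaling, 60 with the slide as a fixed block and 60 to 70 without an array. With an estimated correlation 0 were kept, and 10 were with the 4 arrays as a block besides. In each case below the cause was not tested, except where fewer arrays, a larger required change or an equal shift of all genes account for it. Depth (signal over background) limited the genes tested to 13238 of 18232.

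Scaling moved several counts of called genes. Quantile normalization called 3 genes in EV against control (CAB39L, DMBX1 and SLC27A5, named after their values were seen, as are the single genes below), left the ribosomal proteins there at -0.004 (adjusted p = 0.965, test direction up) and reversed TRAF1 in the interaction (-0.031), and its correlation of the EV and TNF main effects was -0.246. Scaling on the median called 1 in EV against control (DMBX1), 116 in EV+TNF against control, 61 in EV+TNF against EV, 13 in the EV main effect and 274 in the TNF main effect, and reversed TNFAIP3 (-0.018) and ICAM1 (-0.017) in EV+TNF against TNF and TRAF1 in the interaction (-0.069).

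Spike-in scaling called 301 genes in EV against control, 13 in TNF against control, 61 in EV+TNF against control, 1 in EV+TNF against TNF (ME1), 8454 in EV+TNF against EV, 1 in the interaction (ME1), 72 in the EV main effect and 4758 in the TNF main effect. It reversed MHC class I in EV+TNF against EV (-0.603) and there SOD2 (-0.573), TRAF1 (-0.217), IL1B (-0.393), TNF (-0.4), TAPBP (-0.2), TNFRSF21 (-0.066), TRAF3 (-0.061), CYLD (-0.02), SQSTM1 (-0.004) and DUSP4 (-0.11). It also reversed TNF in TNF against control (-0.077), SOD2 in EV+TNF against control (-0.152), TNFAIP3 (-0.099) and ICAM1 (-0.098) in EV+TNF against TNF, TRAF1 (-0.56), BIRC3 (-0.489), CCL2 (-0.456) and TNF (-0.323) in the interaction, and SOD2 (-0.182), TNF (-0.239), PLAUR (-0.022) and CRELD2 (-0.021) in the TNF main effect.

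Normexp with the limit called 6 genes in EV against control and reversed SCRN1 (0.017) and TRAF1 (-0.007) in the interaction. Without it, it called 38 in TNF against control, 72 in EV+TNF against control, 26 in EV+TNF against EV, 9 in the EV main effect and 355 in the TNF main effect. The deposited table gave 5 in EV against control (among them CAB39L, FNIP2, NKX2-1 and SLC27A5) and 1 in EV+TNF against TNF (CYP1A1), a floor on low values gave 7 and a trend with robust spread 6 in EV against control. The mean of the probes reversed TNF in TNF against control (-0.013) and TRAF1 in the interaction (-0.071). With no filter the counts were 42, 138 and 58 in TNF against control, EV+TNF against control and EV+TNF against EV, 30 and 345 in the EV and TNF main effects, and the correlations were 0.26 for EVs with and without TNF, 0.314 for TNF with and without EVs and 0.297 for EV and TNF against control. With the filter on all arrays the correlation for EVs with and without TNF was 0.673.

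With the slide as a fixed block 163 genes were called in EV against control, 41 in TNF against control and 124 in EV+TNF against control, and IL1B reversed in EV+TNF against EV (-0.138). As a random block the slide gave 460, 142 and 458 in the same order, 2 in EV+TNF against TNF (CYP1A1 and MTUS1), 349 in EV+TNF against EV, and 1094 and 1098 in the EV and TNF main effects. The replicate number as a block gave 30 in TNF against control, 113 in EV+TNF against control, 1 in EV+TNF against TNF (MTUS1), 29 in EV+TNF against EV, and 13 and 303 in the main effects. Array weights, which stopped before convergence, gave 3298 in EV against control, 2230 in EV+TNF against control, 1 in EV+TNF against TNF (MTUS1), 4044 in EV+TNF against EV, and 2826 and 1971 in the main effects, and reversed TNF in TNF against control (-0.026), NFKBIA (0.197) and TRAF1 (0.063) in EV+TNF against TNF, and NFKBIA (0.184), TNFAIP3 (0.004) and ICAM1 (0.073) in the interaction.

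The 4 arrays that stood apart as a block gave 1896 in EV against control, 822 in TNF against control, 1661 in EV+TNF against control, 9 in EV+TNF against TNF, 1450 in EV+TNF against EV, and 3145 and 2900 in the main effects. Without these 4 the counts were 542 in TNF against control, 950 in EV+TNF against control, 1 in EV+TNF against TNF (MMP1), 1073 in EV+TNF against EV, and 834 and 2344 in the main effects, and TNF reversed in TNF against control (-0.081) and ICAM1 in the interaction (0.052). A required change of 2-fold left 42, 86 and 45 genes in TNF against control, EV+TNF against control and EV+TNF against EV and 66 and 78 in the main effects, and the arrays of just the 2 groups, with fewer degrees of freedom, 13, 28 and 41 in the same 3 comparisons.

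Leaving out 1 array at a time, the counts ran from 0 to 651 in EV against control, 22 to 84 in TNF against control, 63 to 280 in EV+TNF against control, 0 to 1 in EV+TNF against TNF, 19 to 283 in EV+TNF against EV, 6 to 1272 in the EV main effect and 234 to 838 in the TNF main effect, and stayed at 0 in the interaction. Named genes that changed sign were TNF in TNF against control (-0.129 to 0.157), NFKBIA (-0.447 to 0.245), TNFAIP3 (-0.133 to 0.2), ICAM1 (-0.037 to 0.152), TRAF1 (-0.353 to 0.149) and IL1B (-0.178 to 0.864) in EV+TNF against TNF, and SOD2 (-0.016 to 0.169) and IL1B (-0.174 to 0.825) in EV+TNF against EV. In the interaction they were NFKBIA (-0.414 to 0.277), TNFAIP3 (-0.295 to 0.047), ICAM1 (-0.177 to 0.039), TRAF1 (-0.252 to 0.286), BIRC3 (-0.042 to 0.17), CCL2 (-0.113 to 0.336) and IL1B (-0.718 to 0.324).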

Other observations

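The tests here, except the splits with the 4 arrays as a block, were chosen after the result was seen. So were the gene families, so their percentiles and p-values decide nothing. Histone genes (63) had a median log2 difference of 0.56 in EV+TNF against TNF, with 60 above 0 and 0 called over all genes (unadjusted camera p = 0.00975 with an estimated correlation). The median was 0.40 with spike-in scaling, 0.52 with the slide as a block, and 0.84 and 0.26 within slides 2 and 4. It lay at percentile 100 of 10000 random lists matched on expression (medians -0.097 to 0.005). In the interaction it was 0.41, or -0.16 with spike-in scaling. In TNF against control it was -0.29 (p = 0.103 with an estimated correlation), and -0.069 and -0.27 within slides 3 and 4. Averaged over the family and centred, TNF 1 lay at -0.54, TNF 2 and 3 at -0.20 and -0.18 and control 3 at -0.27.

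The 11 metallothionein genes had a median of -1.88 in the EV main effect, all 11 below 0 and 3 called over all genes (p = 0.0673 with an estimated correlation), at percentile 0 of random lists that ran from -0.16 to 0.093. It was -1.75 with spike-in scaling, -2.05 with the slide as a block and -1.84 with quantile normalization. Averaged and centred over arrays as above, the control arrays lay at -0.30, 0.87 and 1.69 and the TNF arrays at 1.77, 1.39 and -0.48, with the lowest of each on slide 4, and the EV arrays lay between -0.94 and -0.70 with or without TNF.

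PTCRA, a part of the pre-T cell receptor, had a log2 difference of 1.76 in the EV main effect (adjusted p = 0.0752). No member of the T cell list was well above background on all 6 arrays with EVs and on none without.

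Other splits of the arrays into groups of the same sizes were fitted alike. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05: TNF against control called 84 genes, EV+TNF against control 266 and EV+TNF against EV 103, each in 1 of 10 splits, and the highest other split called 0. EV against control and EV+TNF against TNF called 0 in all 10 splits, a count that every split reaches. For the main effects 100 splits were drawn, and 1 of 100, the real one, reached the 516 genes of the EV effect and the 553 of the TNF effect, where the highest other called 1 gene in each, so that a random grouping was excluded. With the 4 arrays as a block, the EV effect called 3145 genes, as 1 of 72 splits did, and the highest other called 2. For the interaction the real split called 0, which all 100 of 100 splits reach whatever they call, so that count says nothing about a random grouping. Of the others 2 called 1032 and 1020 genes, which points to a structure of the samples. The first set 5 of the 6 arrays with EVs on one side of the contrast, and the second all 4 arrays that stood apart.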
